A study of Mus musculus with 12 samples.

How the data were processed

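The study mapped ESRP1 contacts with RNA by eCLIP in epidermis of mouse pups on postnatal day 1, from animals whose endogenous ESRP1 carries a FLAG tag. Per the labels' protocols, epidermal sheets were irradiated with ultraviolet light, FLAG immunoprecipitates and inputs were run on protein gels, and the membrane between 75 and 140 kDa was excised. RNA released from it was made into libraries by the published eCLIP design, in which reverse transcription tends to stop at the crosslinked nucleotide. The labels name 6 immunoprecipitated and 6 input libraries, as biological replicates 1 to 6.

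The values used were 3 lists of sites, 1 per 2 replicates, that the authors deposited. Per the file headers, sites were called with input. Each line is 1 nt wide, names a strand and carries a score, which the authors deposited without a stated scale. PureCLIP, a caller of single-nucleotide crosslink sites, is named in a title in the labels, but which step it stands for is not given in the sources used here. The submitters' processing notes name cutadapt 1.16, HISAT2 2.1.0, HOMER and the builds GRCm38 and mm10, without roles or settings. Adapter trimming, removal of PCR duplicates, treatment of reads with several alignments and calling settings are not given in the sources used here. The highest score was 708.396 in each list (12, 1 and 3 sites), which equals minus the natural log of the smallest normal double-precision number, so the scale ends there. Calling on pooled replicates hides the spread between the 2 replicates of a list. The labels call the replicates biological, and p-values over lists or positions do not measure variation between individual libraries. Subtraction or weighting by input during calling, and an aligner's choice among copies, can both remove or add sites in abundant or repeated genes.

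The annotation used was a table of 49943 genes on GRCm38.p6, the same build, with the start and end of each gene but no exons, transcripts or strand; no genome sequence was used here. Coordinates are 1-based on GRCm38. Sites of a list at most 10 nt apart on a strand were joined into regions, and regions of different lists at most 10 nt apart were called shared. A region was found in all 3 lists when the union region held sites of each. A region was assigned to a protein-coding gene when its middle lay in a single protein-coding span, and 133 regions under several such spans were left out of gene counts. Where spans of several kinds overlapped, the region was counted as tRNA, then other small RNA, pseudogene, protein-coding and last long noncoding RNA. The strand of a gene was taken as the strand with most sites in its span, a choice made after the data were examined. Sites per protein-coding gene were counted on that strand, where no other protein-coding span covered them. A gene given as without a site had none counted in this way.

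Chance sharing was measured from 100 redraws of the other list. Regions under a single protein-coding span were redrawn within that span. All other regions, also those in tRNA, pseudogene or long noncoding RNA genes, were redrawn within 5000 nt and could leave their gene. Gene lists were tested by the number of genes with a region in all 3 lists against 10000 random lists matched on deciles of span length, two-sided, with Benjamini-Hochberg adjustment over 15 lists. These lists hold 372 entries for 362 different genes, and 2 of 374 symbols did not match the annotation. All were fixed from general knowledge before the data were examined, and 1 of them, with some named genes, is not reported here. The others are: ESRP splicing targets, ESRP paralogs and epithelial regulators, adherens junction and desmosome, tight junction, integrin and hemidesmosome, keratins and cornified envelope, RNA-binding proteins, the Wnt group, receptor tyrosine kinases, ribosomal proteins, and markers of melanocytes, dermal fibroblasts, immune cells, and endothelium and muscle. Positions toward gene ends were compared with a sign-flip permutation test over genes with 100000 permutations. Intervals of shares are exact binomial intervals (Clopper-Pearson, 95%) and cover counting error only.

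The design, the rule for named genes and most alternatives were also fixed before the data were examined. The comparison of gene ends with its settings, the count on either strand, the restriction to regions under no other gene and the local redraw were chosen after. That rule took the 15 genes with most regions in all 3 lists, the 10 with the highest mean score percentile of a region, each bound member of the ESRP target list with Esrp1 and Esrp2, and the 4 members with most regions of each other list. Unbound members, Krt1, Krt2 and Krt14, were named after their values were seen, as were the genes given as examples at gene ends.

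Several planned results were not run because they need sequence, exons or gene strand: the share of regions in untranslated regions, coding sequence and introns, the UGG-rich motif at regions, the position within 3′ untranslated regions, and regions beside cassette exons. Shares by kind of gene took the place of the shares by transcript part. The planned redraw within gene and transcript part was replaced by redrawing anywhere in the same protein-coding span, also chosen beforehand. Random lists were matched on span length without exon length. Alternatives tried were another joining distance, another sharing distance, the 50% of each list with the highest scores, each list left out, regions in at least 2 lists, and random lists drawn from genes with a site.

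The procedures were tested on simulated data. For the sharing of list 1 (29037 regions) with a simulated list, planted shares of 0%, 10% and 40% were found as 0.296%, 10.4% and 40.2%. For gene lists over 21887 protein-coding genes, 0 of 210 simulated lists were called when bound genes were drawn at odds of 1, 8.57% at odds of 2 and 51.9% at odds of 3. With 6002 region positions redrawn uniformly, the ratio of 3′ to 5′ ends was 1.01. The simulated data came from the same redraws and span deciles as the tests. They show whether a planted signal is found, but hold no differences between genes in expression, exons or read alignment. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.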

Results

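The RNA contacts of ESRP1, an epithelial splicing regulator, were mapped in mouse epidermis by enhanced crosslinking and immunoprecipitation (eCLIP). In this assay ultraviolet light joins a protein to the RNA it touches, the protein is pulled down, and the points where reverse transcription of the recovered RNA stops mark the contact to the nucleotide. Endogenous ESRP1 carried a FLAG tag on both alleles, and epidermis was taken from back skin of pups on postnatal day 1. The labels list 12 libraries, made of 6 FLAG immunoprecipitations and 6 inputs from biological replicates 1 to 6. The data analysed here were 3 lists of single-nucleotide, strand-specific sites, each called by the authors on 2 replicates together with input. List 1 held replicates 1 and 2, list 2 held replicates 3 and 4, and list 3 held replicates 5 and 6. The lists carry no read counts, so the depth of each library is unknown. Means and SDs are over the 3 lists, and other tests take genes, gene lists or regions as their units. The deposited score of a site is the authors' own value. It was used within a list to rank or filter sites and, in the flagged results, to find repeated series of scores.

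Many ESRP1 sites lay in small clusters on the RNA, though most regions of list 2 were single sites and clustering was not compared with chance. List 1 held 73602 sites, list 2 held 40014 and list 3 held 53864, with median scores of 11.6, 14.7 and 17.7. Joining sites at most 10 nt apart on a strand gave 29037, 24363 and 22840 binding regions. A region of list 1 held 2.53 sites on average, against 1.64 in list 2 and 2.36 in list 3. Regions of a single site made up 39.3% of list 1 (95% exact binomial interval 38.7 to 39.9), 62.0% of list 2 (61.4 to 62.7) and 42.6% of list 3 (41.9 to 43.2). The intervals of list 2 and the other lists did not overlap, but they cover counting error only, and list 2 is a single list.

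Lists from different biological replicates held contacts at the same nucleotides. Of all sites, 14582 fell on exactly the same nucleotide in all 3 lists, which was 19.8% of list 1, 36.4% of list 2 and 27.1% of list 3. Sites with higher scores recurred more often: in list 1, 3.11% of the lowest quartile by score and 52.0% of the highest quartile were found in all 3 lists, against 12.1% and 79.2% in list 2 and 7.43% and 60.8% in list 3. Between any pair of lists, 46.0% to 64.5% of regions lay within 10 nt of a region of the other list. For chance, regions of the other list under a single protein-coding span were redrawn at random within it, and all others within 5000 nt. The shared part was then 0.366% to 0.613%, so that the observed sharing was 105 to 133 times that of chance. The redraws cover introns too, so exon content and other features common to the lists are not separated from binding in this fold. This fold depends on the setting: its mean over the comparisons was 117, against 70.5 when regions were moved by 100 to 1000 nt for chance, 33.8 with sharing within 50 nt, 436 with an overlap of 1 nt and 178 for the 50% of sites with the highest scores. None of 100 redraws reached the observed value in any of the 6 comparisons (one-sided permutation p = 0.0099 in each, the smallest that 100 redraws can give). On the opposite strand no region lay within 10 nt of a region of another list, and 0.612% to 0.893% lay within 1000 nt, against 59.6% to 85.9% on the same strand. The union of the lists formed 45738 regions, of which 26252 came from 1 list, 9837 from 2 lists and 9649 (21.1%) from all 3. The regions found in all 3 lists had a median length of 8 nt and are the set described below.

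**Figure D1:**
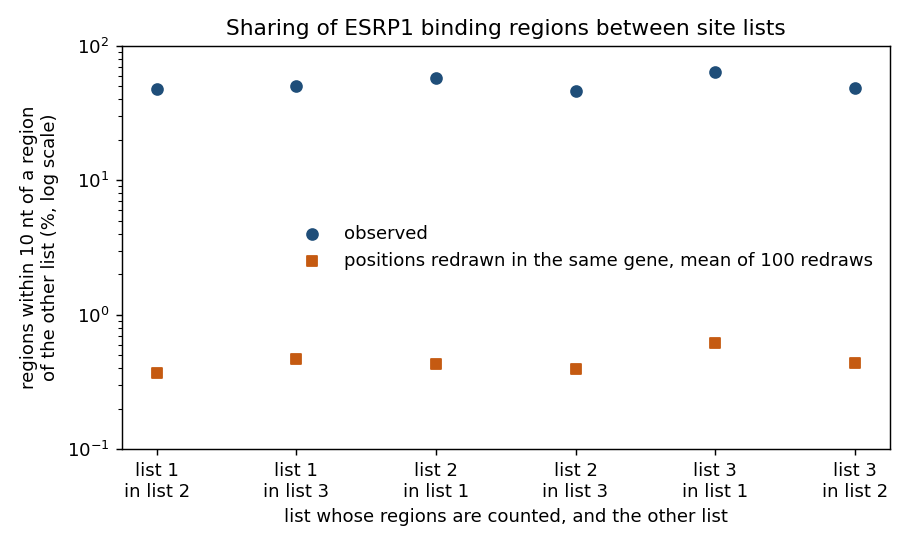
Share of binding regions (%, log axis) that lie within 10 nt of a region of another site list, for the 6 ordered pairs of lists. Circles give observed shares, and squares the mean of 100 redraws of the other list's regions. Regions under a single protein-coding span were redrawn within it, and all others within 5000 nt. Observed values sit between 46.0% and 64.5%, and redrawn values between 0.366% and 0.613%.

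Most ESRP1 regions lay in protein-coding genes. In the GRCm38 annotation, which gives the extent of each gene but not its exons or strand, 70.9% ± 2.64 (SD, n = 3 lists) of regions lay in protein-coding spans. Long noncoding RNA spans held 2.74% ± 0.313, pseudogene spans (those annotated as transcribed left apart) 7.08% ± 0.842 and tRNA genes 0.963% ± 0.266, and 17.5% ± 3.25 lay outside every annotated span. Among regions found in all 3 lists, 6328 (65.6%) were protein-coding, 305 (3.16%) in long noncoding RNA genes, 928 (9.62%) in those pseudogenes, 60 in transcribed pseudogenes, 171 (1.77%) in tRNA genes and 1840 (19.1%) outside every span. Per megabase of span there were 6.13 regions in protein-coding genes, 34.2 in pseudogenes other than transcribed ones, 1.38 in long noncoding RNA genes and 1.25 outside spans. Lengths include parts shared with other kinds of gene, whose regions were counted for a single kind, so the value for long noncoding RNA genes is biased low. In 3853 protein-coding spans with at least 10 sites, 96.5% of sites lay on the strand that held the majority, a share that is high by construction where a single cluster gives most of the sites. Because the annotation used gives no strand, that majority strand stood for the gene's own, which is unsafe where a span holds few sites or a single cluster.

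A region found in all 3 lists was present in 3862 of 21887 protein-coding genes (17.6%). Hrnr, which encodes the cornified envelope protein hornerin, had 15 such regions, but all of them recurred at an exact spacing of 1044 nt and at only 3 positions within it. Ctnnd1, encoding the cadherin partner p120-catenin, had 13. Ahnak, a giant scaffold protein, and Col7a1, the collagen of anchoring fibrils, had 11 each, and Marchf3, a membrane ubiquitin ligase, had 10. Regions numbered 9 each in Ube2k, a ubiquitin-conjugating enzyme, in Skint6, in Jup, which encodes the desmosomal plakoglobin, and in the elongation factor gene Eef2. The remaining 6 of the 15 genes richest in regions were Atp13a3, the polarity gene Pard3, the desmoglein genes Dsg1a and Dsg1b, the cytolinker gene Plec and Cd44, with 8 each.

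Sites in these genes were abundant in each list. Ctnnd1 held 81, 43 and 51 sites in lists 1, 2 and 3, Hrnr 79, 18 and 53, and Col7a1 77, 39 and 54. Most genes had far fewer regions: 2463 genes (63.8%) had 1, 105 had 5 or more and 5 had 10 or more. A total of 4488 genes had a region in each list, counted per gene, where 481 would be expected of independent lists and 907 of lists independent within deciles of span length. All lists come from the same tissue and expression was not measured. This excess therefore does not separate shared binding from shared expression. Genes with a region in all 3 lists were longer than protein-coding genes in general, with a median span of 36542.5 nt against 17169 nt. Several of these genes may share reads with close copies, among them Dsg1a with Dsg1b, the repeats within Hrnr, and Eef2, and their counts are uncertain to that extent. In Skint6, 27 further sites lay on the other strand. Counts per gene rose where fewer lists had to agree: without list 2, Hrnr had 26 regions, Col7a1 18, Skint6 16 and Dsg1a 15, and without list 3, Pard3 had 14.

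Protein-coding genes were also ranked by the best of their regions found in all 3 lists, using the mean percentile of its highest score within each list. The first 10 were Wnt2b, Rbms3, Krt5, Smpx, Sema3e, Atrn, Frmpd2, Hnrnpa1, Mcmdc2 and Actr2. Regions under no protein-coding span, under several or on the strand with fewer sites were not ranked. In 7 of these 10 genes that region was the only one found in all 3 lists. The strand of the genes was taken from the sites, so the lone region in each of these 7 genes (Wnt2b, Rbms3, Smpx, Sema3e, Atrn, Frmpd2 and Mcmdc2) could lie on RNA of the opposite strand or of an unannotated copy. Krt5, the basal keratin gene, and Hnrnpa1, a splicing factor gene, had 7 regions each and Actr2, an actin-nucleating gene, had 3. The Krt5 region covered chromosome 15, 101712458 to 101712460 (GRCm38), 446 nt from the 5′ end of the span on its strand, with highest scores of 390, 279 and 411 in lists 1, 2 and 3. The Wnt2b region covered chromosome 3, 104957682 to 104957692, with highest scores of 493, 288 and 355.

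Genes known for ESRP-dependent splicing were among the bound genes. Of 36 such genes in a list fixed beforehand, 24 had a region in all 3 lists, against 10.4 on average in random lists matched on span length (ratio 2.31). Against random lists of genes with a site the ratio was 1.48 and no longer passed (adjusted permutation p = 0.0530). That adjustment also counted an untested list, which decides this call. Ctnnd1 led with 13 regions, followed by Cd44 with 8, the epidermal transcription factor gene Grhl1 with 7 and the proton pump gene Atp6v1c2 with 5. Ralgps2, Magi1 and Plekha1 had 3 regions each. Fgfr2, whose epithelial and mesenchymal exons are a classic ESRP switch, had 2, as did Enah, Fnip1, Mprip, Itga6, Macf1 and Golga2. A single region was present in Dnm2, Cttn, Arhgef11, Slk, Lrrfip2, Map3k7, Rps24, Scrib and Numb. The strongest Ctnnd1 region covered chromosome 2, 84624709 to 84624711, and the strongest Cd44 region covered chromosome 2, 102834150 to 102834162, both on the minus strand. In Cd44, 5 of the 8 regions lay between 102829425 and 102834162. Both Fgfr2 regions lay close together, at chromosome 7, 130198707 and 130199976 to 130199987, within a span running from 130162451 to 130266808. In Grhl1, 4 of the 7 regions lay between chromosome 12, 24615934 and 24617271, the last of them 122 nt from the end of the span.

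Of the 12 members with no region in all 3 lists, 8 had at least 1 site, Mbnl1 the most with 16, 2 and 10 sites. No site was assigned to Palm, Exoc7, Ktn1 or Osbpl3. Esrp1 itself had 3 regions, with 21, 11 and 12 sites, whereas its paralog Esrp2 had 0, 1 and 5 sites and no region in all 3 lists. Among sites of the 50% of each list with the highest scores, Macf1, Mprip, Rps24, Scrib and Slk had no region in all 3 lists. The Numb region lay under another annotated gene, Gm46367, and could belong to either. Without list 1 the Scrib region was also lost, and without list 2 Fgfr2 had 5 regions, Enah 5, Macf1 7 and Esrp1 6.

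**Figure D2:**
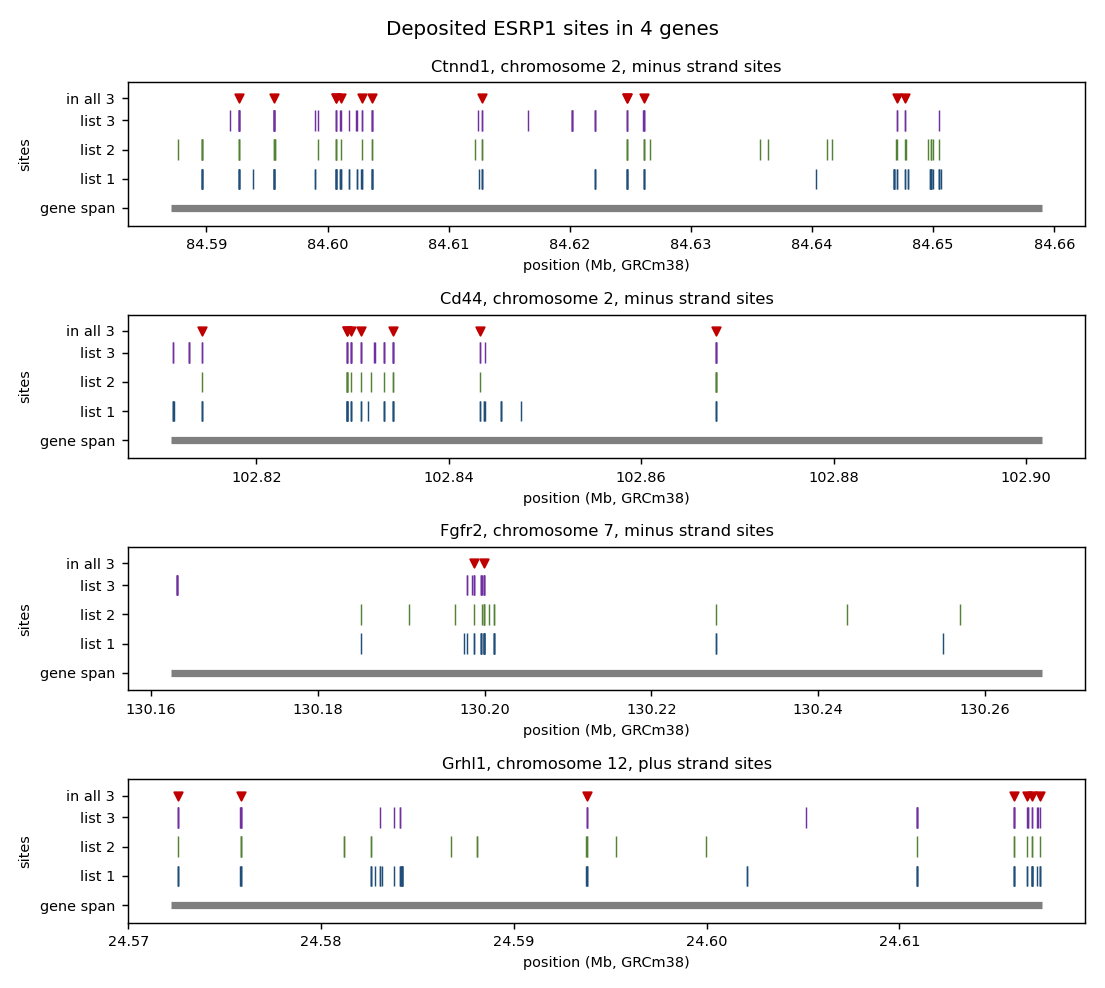
Deposited sites (vertical ticks) of lists 1, 2 and 3 along the spans of Ctnnd1, Cd44, Fgfr2 and Grhl1 (grey bars), on the strand with most sites, against position in Mb (GRCm38). Red triangles mark the 13, 8, 2 and 7 regions found in all 3 lists.

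Adherens junction and desmosome, keratin and cornified envelope, RNA-binding protein and receptor tyrosine kinase genes were bound more often than random lists of matched span. This difference did not pass against genes with a site, in an adjustment that also counted an untested list. Of 15 lists fixed beforehand, 8 passed (permutation test against 10000 random lists, two-sided, Benjamini-Hochberg over the 15 lists), all with more bound genes than random lists. In the adherens junction and desmosome list 16 of 22 genes had a region in all 3 lists (5.34 expected, adjusted permutation p = 0.0005), with 13 regions in Ctnnd1, 9 in Jup, 8 in Dsg1a and 8 in Dsg1b. Among keratin and cornified envelope genes 20 of 38 were bound (4.35 expected, adjusted permutation p = 0.0005), led by Hrnr with 15 (at 3 positions of its repeat), Krt5 with 7, Flg2 with 6 and Krt15 with 3. In that list 8 genes had no site assigned to them in any list, including the abundant keratins Krt14, Krt1 and Krt2. RNA-binding proteins and splicing factors had 25 of 37 genes bound (7.26 expected, adjusted permutation p = 0.0005), with 7 regions in Hnrnpa1, 6 in Hnrnpm and 5 in Hnrnpa2b1. Receptor tyrosine kinase signalling had 16 of 27 (6.55 expected, adjusted permutation p = 0.0005), with 3 regions each in Fgfr3, Braf and Grb2. The ESRP splicing targets passed with 24 of 36 (adjusted permutation p = 0.0005).

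Ribosomal protein genes had 19 of 40 bound (3.78 expected, adjusted permutation p = 0.0005), with 4 regions in Rps3 and 3 each in Rpl23, Rpl11 and Rpl4. These genes have many processed copies in the genome, so their counts are uncertain. The list of ESRP paralogs and epithelial regulators had 9 of 17 (3.60 expected, adjusted permutation p = 0.0124), with 4 regions in Klf4, 3 in Esrp1 and 2 each in Trp63 and Tfap2a. Against random lists of genes with a site, neither the ribosomal list (ratio 1.32) nor the epithelial regulators (1.23) passed. An adjusted p of 0.0005 was the smallest the permutations of the main setting gave.

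Other lists did not pass. The tight junction list had 8 of 21 genes bound (5.26 expected, adjusted permutation p = 0.342), Pard3 with 8 regions, and Magi1 and Cgn with 3 each. The integrin and hemidesmosome list had 6 of 16 (4.15 expected, adjusted permutation p = 0.491), Plec with 8 regions, Col17a1 with 5, Lama3 with 3 and Itga6 with 2. The list of Wnt, Hippo, Notch and TGF-beta signalling had 11 of 30 (7.89 expected, adjusted permutation p = 0.346), Tead1 and Bmpr2 with 5 regions each, Lrp6 with 4 and Yap1 with 3. Markers of other skin cells had few bound genes, and none of these lists passed either. The melanocyte list had 1 of 10 (Mitf, 2 regions, 2.34 expected, adjusted permutation p = 0.593). The dermal fibroblast list had 1 of 17 (Sparc, 1 region, 3.84 expected, adjusted permutation p = 0.221). The immune cell list had 1 of 14 (Csf1r, 2 regions, 2.12 expected, adjusted permutation p = 0.696) and the endothelial and muscle list 0 of 14 (2.67 expected, adjusted permutation p = 0.159). Of these 55 marker genes, 42 had no site assigned to them in any list. Most protein-coding genes likewise had none, as 7895 of 21887 had a site on either strand.

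The lists' calls depended on which genes the random lists were drawn from. Gene expression was not part of the data, so expression could not be matched. When random lists were drawn from the 7895 protein-coding genes with a site on either strand in any list, 0 of 15 lists passed. The endothelial and muscle list kept only 1 gene there, so it was not tested but was still counted in the adjustment. The adjusted values of 0.0530 given next lie near the threshold, and whether they pass depends on that entry. Of the lists, 4 had more bound genes at an unadjusted p under 0.05. The adjusted p was then 0.0530 for the ESRP splicing targets (ratio 1.48), 0.0530 for adherens junction and desmosome (1.72), 0.0530 for RNA-binding proteins (1.49) and 0.0832 for receptor tyrosine kinase signalling (1.54). It was 0.156 for keratins (1.41) and 0.331 for ribosomal proteins (1.32), and 1 for the epithelial regulators. Without list 2, the integrin list passed (adjusted permutation p = 0.0267) and so did the Wnt list (adjusted permutation p = 0.0133), which also passed without list 3 (adjusted permutation p = 0.0236).

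**Figure D3:**
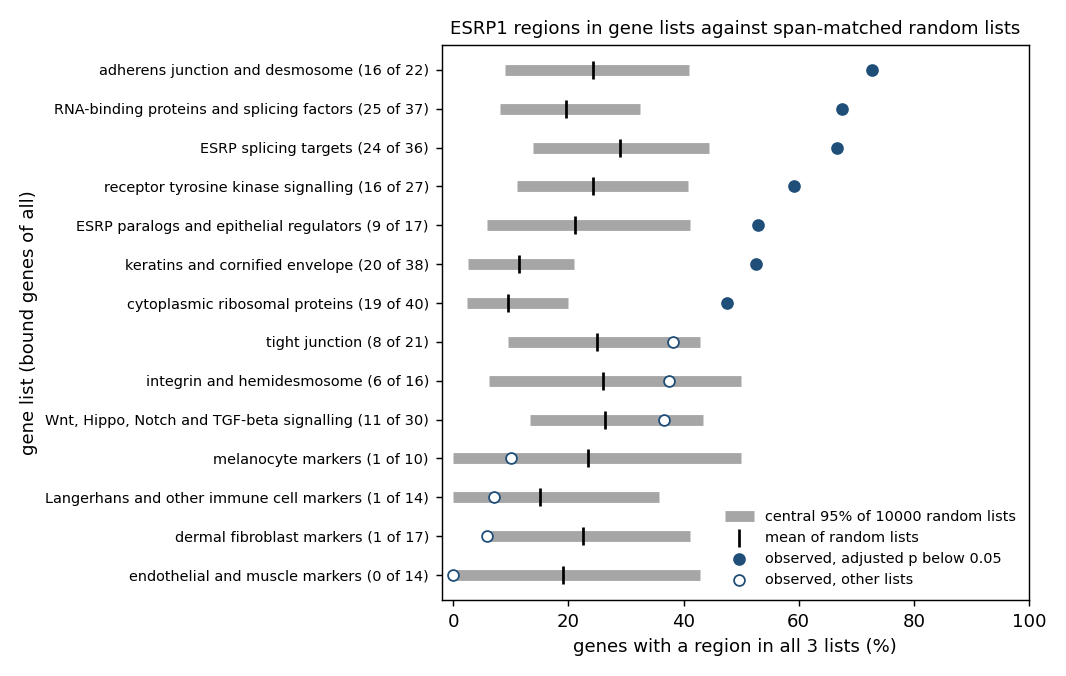
Share of genes (%) with an ESRP1 region in all 3 site lists for the gene lists described (circles, filled where the adjusted p is below 0.05), with the mean (tick) and central 95% (grey bar) of 10000 random lists matched on span length. The filled circles lie right of their bars. With random lists drawn from genes with a site, 0 lists passed in an adjustment that also counted an untested list.

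ESRP1 regions gathered toward the 3′ ends of genes. Of 6002 regions found in all 3 lists in 3654 protein-coding spans of at least 4000 nt, 18.1% lay in the last 1000 nt and 8.46% in the first 1000 nt, where 4.05% would be expected of uniform positions. The last 1000 nt thus held 2.14 times as many regions as the first. More genes had an excess at the 3′ end (841) than at the 5′ end (381; sign-flip permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 permutations can give). Each list showed the same direction, with 16.0%, 12.4% and 19.0% of regions at the 3′ end against 7.53%, 8.04% and 9.14% at the 5′ end in lists 1, 2 and 3. Examples were Dsg1a, whose strongest region (chromosome 18, 20343008 to 20343021) lay 339 nt from the 3′ end, Fgfr3 at 392 nt, Krt15 at 356 nt, Map3k7 at 91 nt and Golga2 at 107 nt. Braf and Krt5 had their strongest region near the 5′ end, at 385 and 446 nt. This comparison was chosen after the data were examined, and without exons a region near the 3′ end could not be assigned to an untranslated region. The uniform expectation covers whole spans, introns included. Without exons, neither the excess over it nor the difference between the ends can be told apart from exon content.

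**Figure D4:**
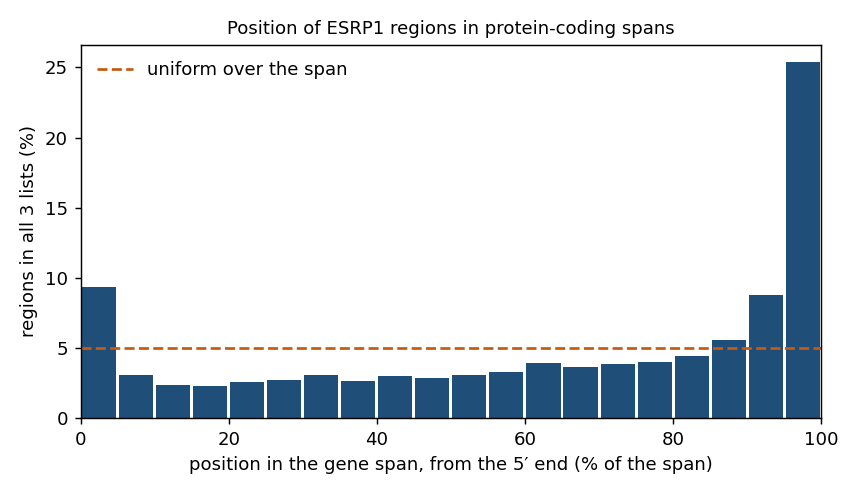
Position of 6002 ESRP1 regions found in all 3 lists along protein-coding spans of at least 4000 nt, from the 5′ end on the strand with most sites (% of the span, 20 equal bins); bars give the share of regions (%) and the dashed line the uniform share. The last bin held 25.4% and the first 9.36%.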

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

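All tests in this part had their expected outcomes written before the tested values were seen, except the share of pseudogenes bound per gene, the opposite-strand count beside gene ends and the counts of regions in all 3 lists with a repeated score series, which were chosen after. The demands made of a value were also tightened after the first values were seen. Under the outcomes first written, both comparisons of repeated score series would have counted for reads aligned to several copies. The share given below for readthrough from a neighbouring gene would have counted against it. No sample group allowed a check for outlying samples, since the lists number 3. The design names no second condition, so no difference between conditions was weighed.

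A signal outside the annotated genes was found: 1840 regions in all 3 lists lay outside every gene span. Among those within 10 kb of a protein-coding span on the same strand, 64.8% lay beyond its 3′ end (136 of 210, 95% interval 57.9 to 71.2, exact binomial p = 2.25e-05), against 43.8% of 89 relative to neighbours on the opposite strand. This is consistent with transcripts that run past the annotated 3′ end, but it concerns 210 of the 1840 regions. Whether reads aligned to several copies add to them cannot be told apart. In the single lists together, series of identical scores repeated elsewhere in a list were 3.45 times as frequent outside spans as in protein-coding spans (0.744% of 8740 regions with several sites, Fisher's exact p = 5.91e-11), but 11 of the 1840 regions held such a series. Neither test accounts for most of the 1840 regions.

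Pseudogenes other than those annotated as transcribed held 928 regions found in all 3 lists, and transcribed pseudogenes 60. Sharing of reads with the parent gene is a candidate explanation: of 133 pseudogenes named after a parent gene that had such a region, 99.2% had a parent gene with a site, against 51.9% of 655 without one (odds ratio 122, Fisher's exact p = 5.79e-32). The test covered 133 of 762 bound pseudogenes, transcribed ones included, and 64 of the 133 were copies of ribosomal genes. Whether transcription of the pseudogenes also adds regions cannot be told apart. Transcribed pseudogenes held 0.358 times as many regions per megabase as the others, which had been set beforehand to count against it, but that bound was wrong because their spans are longer (median 3350 nt against 910 nt). Per gene, 9.69% of 485 transcribed pseudogenes were bound against 7.19% of 9944 others (Fisher's exact p = 0.0486), but longer spans raise this share, so neither measure decides.

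On the strand with fewer sites, protein-coding spans held 126 regions found in all 3 lists and covered by no other annotated gene (160 with those under another gene). Reads aligned to several copies cannot be told apart as a source. Repeated score series were 4.56 times as frequent on this strand as on the main strand in the single lists together (7 of 711 regions with several sites, Fisher's exact p = 0.00145), but only 1 of the 126 regions held one. Readthrough from a neighbouring gene cannot be told apart, because only 3 of the 126 regions lay within 10 kb of a span on their strand, 33.3% of them beyond its 3′ end (interval 0.840 to 90.6).

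On the Y chromosome 17 regions were found in all 3 lists; the sex of the pups is not given in the labels.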

How the results depend on the processing

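The gene end distances, the either-strand count, the restriction to regions under no other gene and the local redraw were chosen after the data were examined; the other alternatives were planned. Sharing was above chance in each setting tried (33.8 to 436 times), and moving regions by 100 to 1000 nt gave chance sharing of 0.760%. Restricting each list to the 50% of sites with the highest scores left 16651, 12888 and 13199 regions in lists 1, 2 and 3 and 6386 in all 3, as fewer sites enter, and moved the protein-coding share to 65.8% and the pseudogene share to 8.64%. Joining only touching sites gave 36134 regions in list 3. Counting each site moved the shares to 65.2% for protein-coding spans, 8.58% for pseudogenes and 21.2% outside spans; the cause was not tested. With random lists drawn from genes with a site, 0 gene lists passed, with 4 at an unadjusted p under 0.05. That adjustment also counted an untested list, and that background holds only genes with some signal. Requiring at least 2 lists brought the integrin list (adjusted permutation p = 0.00720) and the Wnt list (0.00167) past the threshold, and the endothelial and muscle list (0 bound, 0.0240) below chance. The other 50 values of the main results were unchanged in direction and call or stayed within 1.5 times or 1 SD. The excess at 3′ ends held at 500 nt (1.58 times), 2000 nt (2.66 times) and with each list left out (1.96 to 2.41 times). For 38 named genes, 270 of 342 region counts stayed within 1.5 times, and 8 in 7 genes fell to 0. No paired analysis was possible because the lists hold pooled replicates and no value per library. Alternatives needing exons, transcripts or sequence were not run: all those of the motif, of 3′ untranslated regions and of cassette exons, the orders of transcript parts, and exon length matching. Depth per library is unknown, so missing sites do not show absence of binding.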

Other observations

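The tests and groupings in this part were chosen after the data were seen, and no hypothesis is attached to them. Besides protein-coding genes, ESRP1 regions found in all 3 lists lay in 243 of 12736 long noncoding RNA genes (1.91%). Their density was 1.38 regions per megabase, beside 1.25 outside every span, but it is biased low. Span shared with other kinds of gene counts in the length, while regions there were counted for the other kind. Gm16630 had most, 13 regions, and Gm30362, whose span lies inside it, had 8. Gm16630 also had 147, 139 and 179 sites in lists 1, 2 and 3, counted per gene rather than within those regions. These spans hold 48 and 18 tRNA genes, and how many of the sites belong to the tRNA genes was not counted. The abundant nuclear transcript Malat1 had 7 regions, with 21, 8 and 15 sites, and Neat1, the scaffold of paraspeckles, had 3, with 20, 15 and 11 sites. The cytoplasmic Norad had 6 regions, which also fall in the overlapping gene Gm14170, and the imprinted H19 had 4.

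Transfer RNA genes were dense in regions, with 171 regions in 121 of 408 genes (29.7%). Their density was not compared with chance, and the amount of each RNA was not measured. Whether the density reflects a preference of ESRP1 for these RNAs was therefore not tested. Regions were found in 14 of 16 proline tRNA genes (87.5%), 11 of 16 glutamine genes, 34 of 57 cysteine genes and 16 of 28 glycine genes. None were found in 33 alanine genes, 20 glutamate genes or 16 methionine genes, and 1 was found among 26 lysine genes. Copies of a tRNA gene are close to identical, so a region in a given copy is uncertain, the genes are not independent, and differences between amino acids were not tested.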
